A study of Mus musculus with 4 samples.

How the data were processed

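RNA abundance was measured in 4 samples of mouse bone marrow cells, each on 1 Affymetrix oligonucleotide array. The starting cells were lineage-negative, Sca-1-positive and c-kit-positive (LSK), a fraction rich in blood stem and progenitor cells. One sample had received a β-catenin retrovirus and one an enhanced green fluorescent protein (eGFP) retrovirus, and both were collected at day 3. The other 2 samples, named DKmix by the submitters, were β-catenin-transduced LSK cells kept in culture to day 50 and day 300. Per the labels' protocols, the medium held serum and the cytokines IL-3, SCF, Flt3 and IL-11, and biotin-labelled cRNA was made from total RNA. Each group held 1 array, so there were no replicates, no test was possible and no p-value is given. The number of arrays limits the precision of every value.

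The deposited values were linear signal intensities, 1 per probe set and array, made with MAS5 per the submitters' processing notes. The MAS5 version, detection calls and a genome build were not given in the sources used here. The 4 arrays held 45101 probe sets each, and on each array the mean intensity after trimming 2% at either end was 150, so the deposited intensities had already been scaled to a common level. Scaling to equal trimmed means therefore left the values as they were. Array medians were 49.6 for β-catenin day 3, 50.2 for eGFP day 3, 54.9 for DKmix day 50 and 39.7 for DKmix day 300.

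Gene symbols came from the annotation table of the array platform. Of the probe sets, 34958 had 1 gene symbol, 932 had several and were given no name, and 9211 were unnamed in the table given. By Entrez identifier, 34754 of the single-symbol probe sets matched a RefSeq gene table, and 0 symbols needed updating. The 64 control probe sets were left out after scaling. Each of 18193 genes took the value of its probe set with the highest mean log2 intensity over the 4 arrays, and 9010 genes had 2 or more probe sets. List entries with no single-symbol probe set in the table given, Trp53 and Ly6a among them, were not analysed here.

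Intensities below a floor of 48.3, the median of all values pooled over the arrays, were set to the floor before taking log2. A ratio with 1 array at the floor is a lower bound, written as "at least", and a gene at the floor on both arrays was not measured in that comparison. Genes above the floor numbered 11212 (61.6%) on the β-catenin day 3 array, 11282 (62.0%) on eGFP day 3, 11691 (64.3%) on DKmix day 50 and 10294 (56.6%) on DKmix day 300. Genes were counted as higher or lower at a ratio of at least 2-fold.

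The 4 comparisons were β-catenin day 3 over eGFP day 3, DKmix day 50 over β-catenin day 3, DKmix day 300 over β-catenin day 3, and DKmix day 300 over DKmix day 50. A further count took genes whose lower DKmix value was at least 2-fold above the higher day 3 value, or the reverse. The only error measure within these arrays was the disagreement of probe sets of the same gene. It was taken as the SD, over genes with 2 probe sets above the floor, of the difference between their log2 ratios, divided by the square root of 2. It covers probe and annotation differences and leaves out differences between cultures.

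The 24 gene lists were β-catenin and Wnt pathway components, β-catenin/TCF targets, stem and progenitor, myeloid, erythroid and megakaryocytic, and lymphoid transcription factors, chromatin and Polycomb regulators, stem and progenitor surface markers, neutrophil genes, monocyte, macrophage and dendritic cell genes, mast cell, basophil and eosinophil genes, erythroid genes, megakaryocyte and platelet genes, B and T lymphocyte genes, stromal and endothelial genes, cell cycle genes, cyclins with CDK inhibitors and the p53 axis, telomere maintenance, apoptosis regulators, interferon-stimulated genes, Notch pathway, ribosome biogenesis, housekeeping and sex-linked genes. Of the 30 matched mast cell list members 1 was also in another list, as was 1 of the 22 neutrophil members. For each list the median log2 ratio of the measured members was placed among 10000 random lists of the same size, matched on mean intensity in 20 bins. The percentile is a description of these arrays. A list was said to stand apart below percentile 2.5 or above 97.5 with at least 5 measured members.

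The comparisons, lists, floor, thresholds, alternatives and the rule for named genes were chosen before the data were examined. The named genes of a comparison were Ctnnb1, the 10 highest and 10 lowest ratios among genes whose brighter intensity was at least 4 times the floor, up to 4 members of each list (6 for transcription factor lists) with the largest ratios past 2-fold, and the housekeeping and sex-linked genes. A gene named in 1 comparison may be given its value in the others.

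The alternatives were the deposited scale, quantile normalization, lowess centring on mean log2 intensity with a fraction of 0.3, a floor of 11.0 (percentile 25) or 134.6 (percentile 75), the mean of all probe sets of a gene, leaving out probe sets marked as able to hybridise to several transcripts, and a 4-fold threshold. A scale set on the hybridisation controls was added after the data were seen. The procedure was tested on simulated arrays of 18193 genes with each comparison's probe set spread, as a robust SD from median absolute deviations. It recovered 98% of genes raised and 84% of genes lowered by 2.0 on the log2 scale for β-catenin over eGFP, 84% and 74% for DKmix day 50 over β-catenin day 3, 94% and 86% for DKmix day 300 over β-catenin day 3, and 90% and 88% for DKmix day 300 over day 50. The raised and lowered genes were drawn from those above the floor on both arrays, so these shares do not cover genes at the floor. The spread was also taken from probe sets above the floor on both arrays and was the same at every intensity. The simulated counts of unchanged genes past 2-fold given below therefore may not hold for genes near the floor. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.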

Results

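The 4 arrays followed mouse LSK bone marrow cells from the first days after retroviral transduction into long-term culture. The series was set up to find genes through which β-catenin, the transcriptional effector of Wnt signalling, acts in the immortalization of blood stem cells, with attention to transcription factors. It combined a pairwise comparison at day 3 with a time course of the β-catenin-transduced culture. With 1 array per group, all differences below are between single arrays and have no replicate check.

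Ctnnb1, the gene for β-catenin, was read by 3 probe sets. The brightest gave 4492 on the β-catenin day 3 array and 4732 on the eGFP day 3 array, with 6034 at DKmix day 50 and 3132 at DKmix day 300. A second probe set gave 1065 with β-catenin and 179.6 with eGFP at day 3, a 5.93-fold difference, then 693.4 and 838.8 on the DKmix arrays, which were 3.86-fold and 4.67-fold above eGFP. A further one was 2.26-fold higher with β-catenin than with eGFP at day 3 (678.6 against 300.8), and the DKmix arrays were 1.56-fold and 1.61-fold above eGFP by it, short of 2-fold. The labels do not say which part of the transcript the vector carried, so the brightest probe set may or may not have seen it.

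RNA quality controls differed between the arrays in another way than the groups. The ratio of 3′ to 5′ signal of Gapdh was 1.18 on β-catenin day 3 and 1.06 on DKmix day 300, and 4.14 on eGFP day 3 and 4.96 on DKmix day 50. For β-actin the ratios were 1.32, 1.20, 1.83 and 3.41 in the same order of arrays. The bacterial control thr gave 3.12, 2.43, 19.5 and 14.8, lys gave 0.804, 1.06, 0.969 and 2.26, and trpn gave 1.18, 1.28, 1.65 and 5.22. DKmix day 50 was the highest by Gapdh, β-actin, lys and trpn, and by lys the eGFP array lay among the other 2. The Gapdh, β-actin and trpn ratios of β-catenin day 3 and DKmix day 300 were alike. The hybridisation controls bioB, bioC, bioD and cre (9 probe sets) were brighter on the DKmix arrays than on β-catenin day 3, by a mean log2 of 0.94 at day 50 and 1.04 at day 300, so the ratios given here rest on equal overall intensity and not on these controls.

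**Figure D1:**
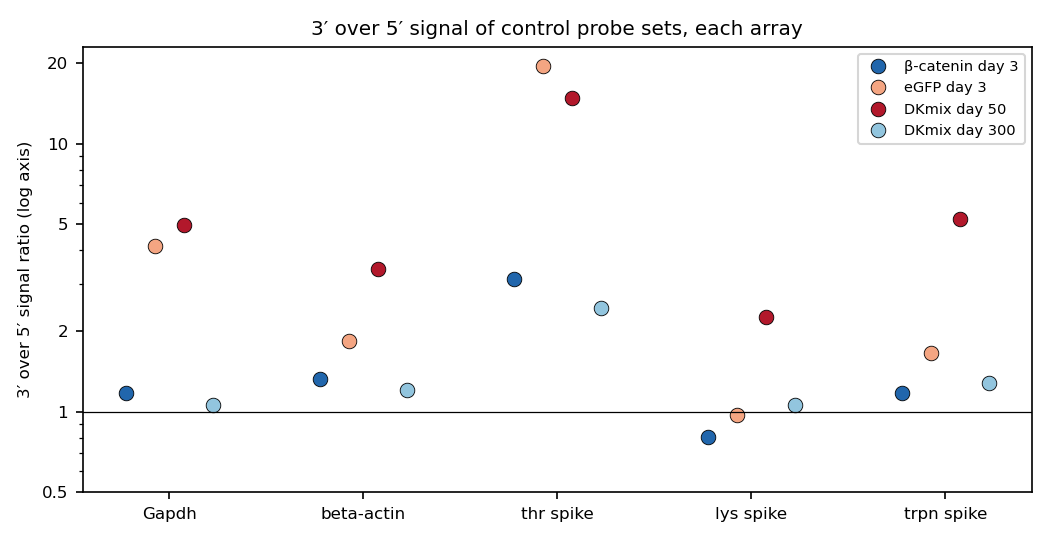
Ratio of 3′ to 5′ signal (log axis) of 2 mouse control genes and 3 bacterial spikes, 1 point per array. The eGFP day 3 and DKmix day 50 points lie above those of the other arrays for Gapdh (4.14 and 4.96), β-actin, thr and trpn, and for lys only the DKmix day 50 point does (2.26).

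Of the 24 lists, neutrophil genes had the median farthest from 0 between β-catenin and eGFP cells at day 3. Ngp, a neutrophil granule protein, was 135-fold lower with β-catenin, S100a9 and S100a8, which form calprotectin, were 96.9-fold and 40.3-fold lower, and lactoferrin (Ltf) was at least 83.2-fold lower. Of 22 measured neutrophil genes, 17 were at least 2-fold lower and 0 were higher, with a median log2 ratio of -1.83 (percentile 0). Lcn2, another granule gene, was alike on both arrays (log2 ratio -0.065). Progenitor genes went the other way: Cd34, a progenitor surface sialomucin, was 7.19-fold higher with β-catenin and Eng, the endoglin co-receptor, 4.90-fold higher.

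Among 23 stem and progenitor surface markers, 7 were at least 2-fold higher with β-catenin and 3 were lower, with a median of 0.80 (percentile 100). The lower members included Cxcr4, the chemokine receptor that retains cells in the marrow (log2 ratio -1.60), and Prom1, at least 19.7-fold lower. Of 34 stem and progenitor transcription factors, 12 were higher and 3 lower, with a median of 0.38 (percentile 99.7). Sox4 was 6.85-fold higher, Gata2 3.68-fold, and Hoxa9, Gfi1 and Erg at least 5.51-fold, 5.46-fold and 3.77-fold higher.

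The myeloid transcription factors went both ways: 8 of 31 were at least 2-fold higher and 5 lower, with a median of 0.40 (percentile 98.6). Cebpb and Cebpd, factors of granulocyte and macrophage differentiation, had log2 ratios of -2.39 and -2.12, and Mxd1, an antagonist of MYC, -2.71. Junb and Relb, an NF-κB subunit, were higher, at log2 ratios of at least 2.67 and of 2.05. Klf1, the erythroid master regulator, had a log2 ratio of -2.60, while Bcl11a was higher at 2.82. The erythroid genes had a median of -0.58 (12 measured, percentile 1.2), with Epor, the erythropoietin receptor, at -1.04.

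Ribosome biogenesis genes were higher with β-catenin, with a median of 0.70 over 30 genes (percentile 100), 8 at least 2-fold higher and 0 lower. Wdr74, Rrp9 and Nle1, which act in pre-ribosome assembly, had log2 ratios of 2.12, 1.96 and 1.75. Interferon-stimulated genes had a median of 0.43 (26 measured, 9 higher, 0 lower, percentile 98.4), among them Gbp2 (at least 5.92-fold) and Ifit1 (log2 ratio 1.36). The monocyte, macrophage and dendritic cell list did not stand apart (median 0.21, percentile 85.2), yet 13 of its 27 measured members were higher and 7 lower. Cd86, a costimulatory ligand, was at least 11.5-fold higher, and Mpeg1, a macrophage perforin, was 11.6-fold lower. Outside the list, Ccr7, a chemokine receptor of mature dendritic cells, was at least 18.5-fold higher. The mast cell list also split, with 8 of 22 higher and 6 lower (median -0.20, percentile 24.4), as with Cpa3 (11.6-fold higher) and Ltc4s (12.9-fold lower).

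The β-catenin/TCF targets did not stand apart at day 3. Of 18 measured, 4 were at least 2-fold higher and 3 lower, with a median of -0.13 (percentile 34.6). Nkd1, a feedback inhibitor of Wnt signalling, was 2.42-fold higher and Jun at least 3.41-fold higher, whereas Id2 had a log2 ratio of -3.33 and Ppard was at least 6.92-fold lower. The Wnt pathway components had a median of -0.056 (percentile 40.9). In all, 7 of the 24 lists stood apart, and the medians of the other 17 lay between -0.45 and 0.31.

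Over all genes, 1365 were at least 2-fold higher with β-catenin and 1258 lower, of 13374 measured. On the scale set on the hybridisation controls, 3124 were higher and 1005 lower. The probe set SD was 0.64 (3626 genes), and an unchanged pair of arrays simulated with its robust form, 0.61, gave 1008 genes past 2-fold. The eGFP array had the higher 3′ to 5′ ratios by each control, though by little for lys, and these accompanied every group described for this pair. With the higher floor the surface marker (median 0.23), interferon (0.15), myeloid factor (0.21) and erythroid (-0.31, 4 genes) lists no longer stood apart, nor did the stem factor (0.22) and myeloid factor (0.20) lists with the mean of all probe sets.

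**Figure D2:**
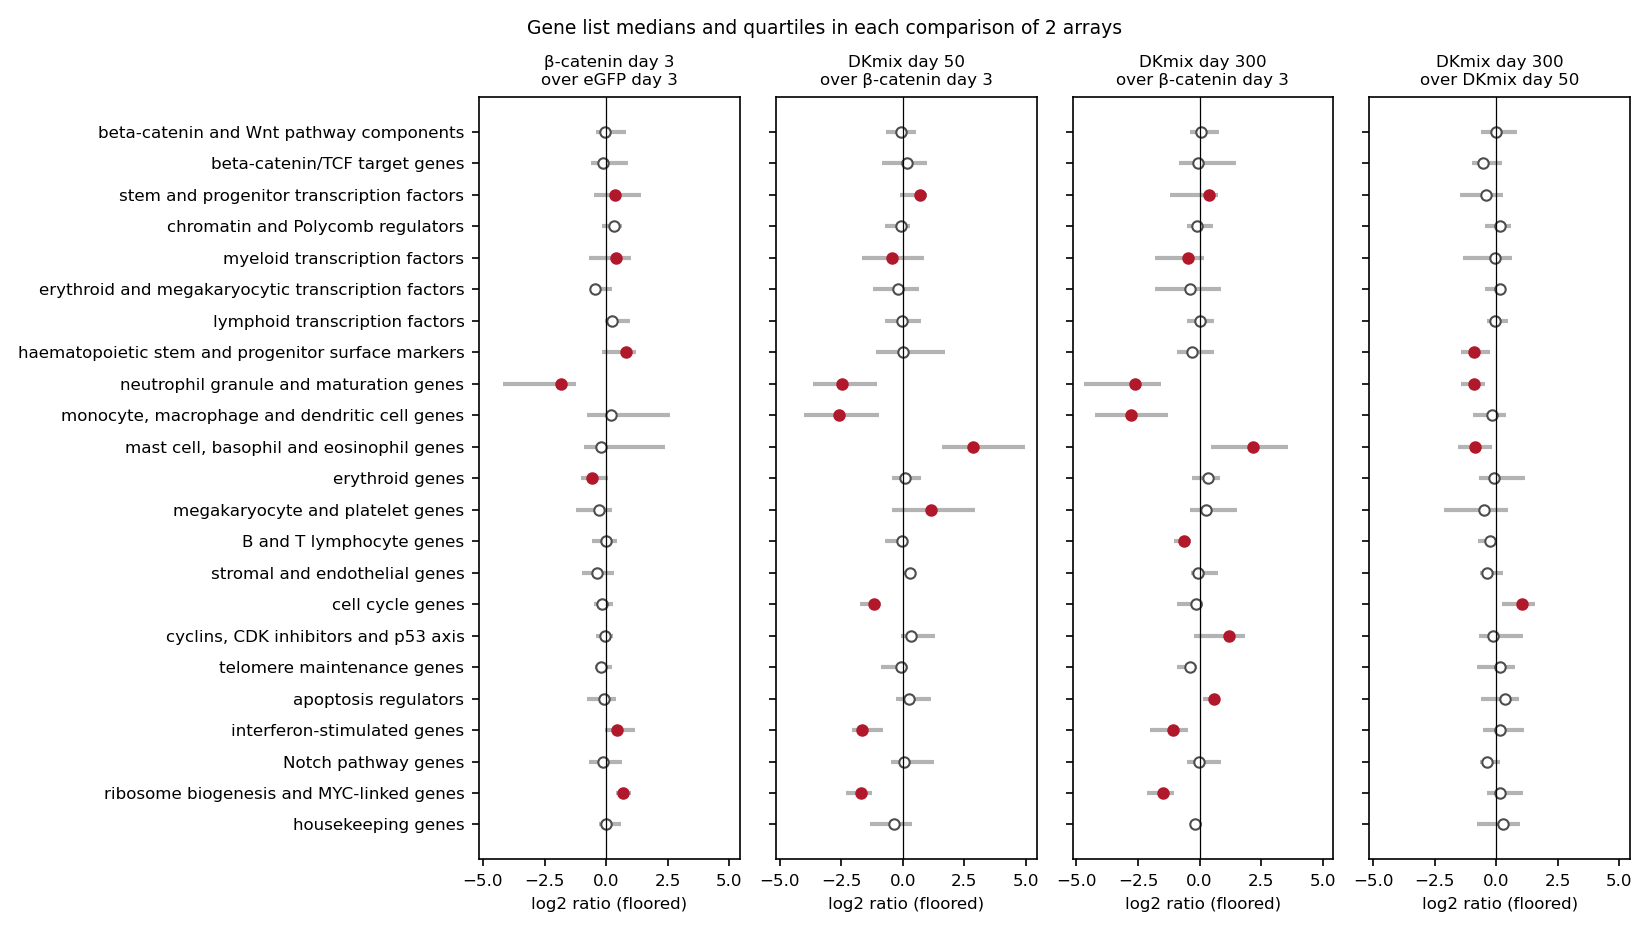
Median log2 ratio of each gene list shown (points) with its lower and upper quartile (grey lines) in the 4 comparisons, each between single arrays. The sex-linked list is left out. Red points are lists that stood apart from random lists and open points are the others. The mast cell list lies at 2.86 and 2.18 in the DKmix comparisons with β-catenin day 3, and the neutrophil list is below 0 in all 4.

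Between day 3 and day 50, on the scale used here, the list of mast cell genes had the median farthest from 0 in the β-catenin-transduced cells. With the scale set on the hybridisation controls its median was 1.92, and the monocyte, macrophage and dendritic cell list lay farthest, at -3.24. Cma1, the mast cell chymase, went from 6.9, below the floor, to 46986, at least 973-fold higher, and the tryptase Tpsb2 and the protease Mcpt2 were at least 120-fold and 103-fold higher. Tph1, which makes serotonin, was 74.7-fold higher and Kit, the receptor for stem cell factor, 41.7-fold higher. Kit belongs to the surface marker list, which did not stand apart (8 of 22 higher, 6 lower, median 0.0057, percentile 41.3). Of 23 measured genes of the mast cell, basophil and eosinophil list, 19 were at least 2-fold higher and 2 lower, with a median of 2.86 (percentile 100). One of the lower members was Hdc, histidine decarboxylase, at least 4.84-fold lower.

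Transcription factors went both ways at day 50. Mitf, a mast cell regulator, was 18.2-fold higher, Gata1 8.93-fold, Gata2 5.56-fold, Fli1 5.07-fold and Tal1 4.42-fold. The stem and progenitor factors as a list had a median of 0.69 (31 measured, 8 higher, 7 lower, percentile 99.6), and Sox4 and Etv6 were lower, at log2 ratios of -3.78 and -2.33. The erythroid and megakaryocytic factors did not stand apart (10 measured, 2 higher, 4 lower, median -0.21, percentile 33.7), with Bcl11a at -2.21, Nfe2 at -1.26 and Zfpm1 at -1.12. The megakaryocyte and platelet genes had a median of 1.14 (15 measured, percentile 100), with 8 higher, such as Vwf (at least 29.2-fold) and Rab27b (32.8-fold, also a mast cell list member), and 3 lower, such as Pf4 (11.2-fold) and Thbs1 (at least 46.6-fold).

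The neutrophil list and the monocyte, macrophage and dendritic cell list were low at day 50. The class II molecules H2-Aa and H2-Eb1 were at least 174-fold and 64.2-fold lower than at day 3, and Cd74, the invariant chain, 131-fold lower. In the monocyte, macrophage and dendritic cell list 20 of 27 genes were at least 2-fold lower and 2 higher (median -2.58, percentile 0). In the neutrophil list 15 of 19 were lower and 1 higher (median -2.45, percentile 0), with Prtn3 at least 88.1-fold and Lcn2 at least 25.6-fold lower. The myeloid factors Cebpa, Irf8 and Relb were lower, by 5.46-fold, at least 4.56-fold and at least 10.6-fold, in a list with 12 of 32 lower and 8 higher (median -0.45, percentile 2.3).

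Growth-related lists were lower at day 50. All but 3 of 30 ribosome biogenesis genes were at least 2-fold lower (27 genes, median -1.68, percentile 0), Wdr74 by 10.8-fold. Of 36 cell cycle genes, 23 were lower and 0 higher (median -1.18, percentile 0), with Plk1, a mitotic kinase, 13.8-fold lower and Tk1, a thymidine kinase, at least 12.3-fold lower. Interferon-stimulated genes had a median of -1.67 (percentile 0), with 19 of 27 lower and 1 higher. Cdkn2a and Cdkn2c, which encode inhibitors of cyclin-dependent kinases, were at least 5.96-fold and 5.45-fold higher, and Trp53inp1, a p53 target, 13.4-fold higher, in a list of cyclins, CDK inhibitors and p53-axis genes that did not stand apart (8 of 28 higher, 2 lower, median 0.34, percentile 90.9). Of the β-catenin/TCF targets, Axin2, a negative regulator of the pathway, was at least 5.95-fold and Id2 23.7-fold higher, while the list had a median of 0.15 (percentile 49.3). Id2 was more than 2-fold lower on the β-catenin day 3 array, the reference here, than on eGFP day 3.

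Over all genes, 2203 were at least 2-fold higher at day 50 and 2162 lower, of 13749 measured, and 9 of the 24 lists stood apart. On the scale set on the hybridisation controls, 700 were higher and 5593 lower. The probe set SD was 0.80 (3585 genes), and the simulated unchanged pair gave 2202 genes past 2-fold. The DKmix day 50 array carried the higher 3′ to 5′ ratios beside each of these groups. The myeloid factor list no longer stood apart under 4 alternatives, with medians between -0.45 and -0.36, and the megakaryocyte and stem factor lists lost their calls, at 0.29 and 0.33, with the mean of all probe sets. With the scale set on the hybridisation controls, the megakaryocyte and stem factor medians were 0.076 and -0.27.

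Mast cell genes were high at day 300 as well. Compared with β-catenin day 3, an array with like control ratios, Cma1 was at least 349-fold higher, Tph1 61.4-fold and the IgE receptor chain Fcer1a 21.3-fold. The monoamine transporter Slc18a2 had a log2 ratio of 4.64, and Kit, of the surface marker list, was 15.2-fold higher. Of 23 measured mast cell list members, 15 were at least 2-fold higher and 1 lower, with a median of 2.18 (percentile 100). Mitf, Gata1 and Gata2 were 12.3-fold, 7.34-fold and 5.12-fold higher.

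The neutrophil list and the monocyte and dendritic cell list were low at day 300 as well. Prtn3, Ctsg and Mpo, proteins of primary granules, were at least 88.1-fold, 92.1-fold and 46.2-fold lower, and 14 of 17 neutrophil genes were lower with 0 higher (median -2.61, percentile 0). H2-Aa was at least 174-fold and Cd74 77.5-fold lower, in a monocyte and dendritic cell list with 22 of 27 lower and 2 higher (median -2.79, percentile 0). Ifitm3, an antiviral membrane protein, was at least 71.4-fold lower, with 14 of 26 interferon-stimulated genes lower and 0 higher (median -1.09, percentile 0). The B and T lymphocyte list had a median of -0.63 (14 measured, percentile 2.2), though Lat, a T cell and mast cell signalling adaptor, was 17.4-fold higher.

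The transcription factors took separate courses. Of the stem and progenitor factors, Hlf was 5.32-fold and Pbx3 at least 7.52-fold higher, while Sox4, Myb and Mycn had log2 ratios of -4.21, -2.49 and -2.49 and Hoxa9 was at least 5.51-fold lower. The list held 7 higher and 10 lower of 32, with a median of 0.39 (percentile 98.8) and a mean of -0.068, and its median was -0.0046 with the mean of all probe sets. The myeloid factors had 10 of 29 lower and 5 higher (median -0.47, percentile 1.6), with Cebpa at least 12.2-fold and Stat5a 7.30-fold lower and Klf2 7.95-fold higher. Among erythroid and megakaryocytic factors the median was -0.37 (percentile 16.9), with Gata1 higher and Bcl11a at a log2 ratio of -2.01.

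Ribosome biogenesis genes were lower at day 300, with 23 of 30 at least 2-fold lower and 0 higher (median -1.49, percentile 0), led by Mybbp1a (8.59-fold). The list of cyclins, CDK inhibitors and p53-axis genes was higher, with 14 of 27 higher and 4 lower (median 1.19, percentile 100). Cdkn2c was at least 11.7-fold higher, Trp53inp1 5.23-fold and Rbl2, a pocket protein of the retinoblastoma family, 4.91-fold. Apoptosis regulators had a median of 0.57 (24 measured, 4 higher, 1 lower, percentile 98.8), with the p53 target Bbc3 4.00-fold and Bak1 3.97-fold higher. Cell cycle genes did not stand apart (median -0.15, percentile 31), with Mcm5 at a log2 ratio of -2.29 and Foxm1 at 2.16.

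The remaining lists did not stand apart at day 300. Medians were 0.063 for Wnt pathway components, -0.061 for β-catenin/TCF targets, -0.091 for chromatin regulators and -0.030 for the Notch pathway. Among the targets, Id2 was 11.2-fold and Ppard at least 8.87-fold higher. Both were more than 2-fold lower on the β-catenin day 3 array, the reference here, than on eGFP day 3. Surface markers had a median of -0.32, with Cd34 5.34-fold higher and Thy1 at least 48.9-fold lower. Erythroid genes (0.36), megakaryocyte genes (0.27), lymphoid factors (0.0075), telomere maintenance genes (-0.37), stromal genes (-0.081), housekeeping genes (-0.20) and sex-linked genes (-0.22) completed the set.

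Over all genes, 1773 were at least 2-fold higher at day 300 and 1828 lower, of 12664 measured, and 10 lists stood apart. On the scale set on the hybridisation controls, 559 were higher and 6049 lower. The probe set SD was 0.64 (3608 genes), the simulated unchanged pair gave 1048 genes past 2-fold, and a second probe set had the direction of the first for 83.7% of the genes past 2-fold. The stem factor list lost its call under 3 alternatives, the apoptosis list with the higher floor (median 0.50) and the mean of all probe sets (0.32), and the lymphocyte list with the higher floor, which left 3 genes (-0.37). With the scale set on the hybridisation controls, the stem factor and apoptosis medians changed sign, to -0.53 and -0.47. The cyclin and p53-axis list kept its call with the mean of all probe sets at a median of 0.69, and its median was 0.14 on the hybridisation control scale.

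**Figure D3:**
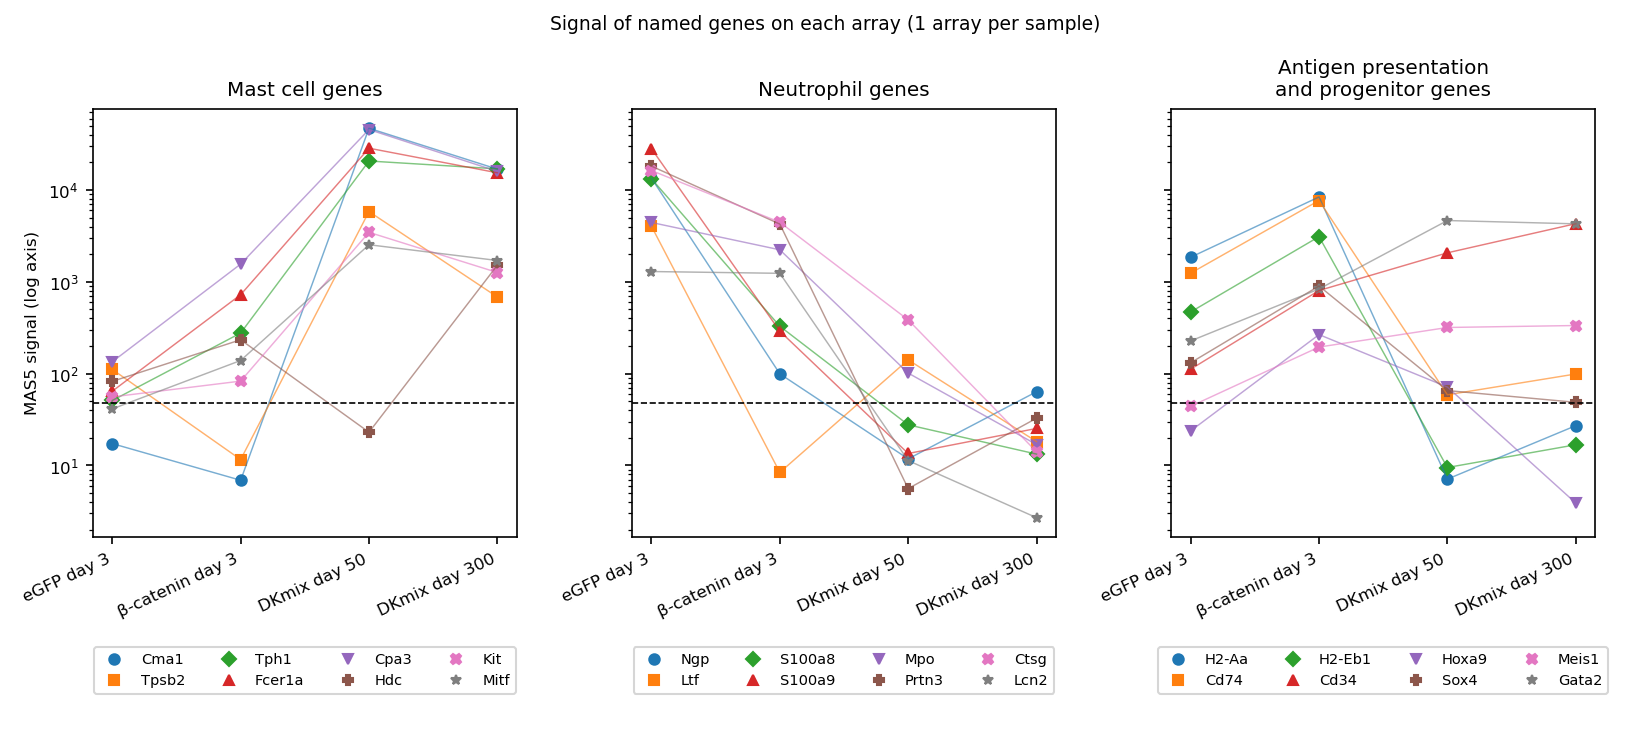
Array intensity (log axis) of 8 mast cell, 8 neutrophil and 8 antigen presentation or progenitor genes on the 4 arrays, 1 point per array, with thin lines only to guide the eye and the floor of 48.3 dashed. Genes were picked for display after their values were seen. Kit and Mitf, shown with the mast cell genes, belong to other lists. Cma1 lies below the floor on both day 3 arrays and at 46986 and 16866 on the DKmix arrays.

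Between day 50 and day 300, individual mast cell proteases and cell cycle genes differed. Mcpt2 was 93.8-fold and Tpsb2 8.52-fold lower at day 300, Gzmb, a cytotoxic serine protease, 28.8-fold lower, and Hdc at least 31.4-fold higher. The mast cell list had a median of -0.85 (24 measured, 2 higher, 11 lower, percentile 0.2). Cell cycle genes had a median of 1.06 (35 measured, 18 higher, 3 lower, percentile 100), with Plk1 12.8-fold and Bub1, a spindle checkpoint kinase, 4.81-fold higher at day 300.

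Surface markers of stem and progenitor cells were lower at day 300, with 8 of 18 lower and 3 higher (median -0.90, percentile 0.5), among them Cd48 (at least 13.6-fold) and Cd93 (4.99-fold). Of the residual neutrophil genes, 5 of 10 were lower and 1 higher (median -0.92, percentile 0.7). Transcription factors with log2 ratios past 1 included Etv6 at 2.93, Gfi1b at 2.82 and Klf2 at 3.33, and Myb at -2.59, Lyl1 at -2.19 and Egr1 at -2.02. Ccnd1, which encodes cyclin D1, was 6.69-fold higher, Cdkn2a at least 5.96-fold lower and Axin2 3.15-fold lower. Igfbp4 (at least 79.8-fold), Plod2, a collagen lysyl hydroxylase (35.1-fold), and Eno3, a muscle enolase (28.7-fold), were among the genes highest at day 300.

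Over all genes, 1972 were higher and 2075 lower, of 13100 measured, and 4 lists stood apart. The simulated unchanged pair gave 2886 genes past 2-fold, the probe set SD was 0.91 (3548 genes) and a second probe set had the same direction for 62.4% of genes past 2-fold. The 3′ to 5′ ratios were high at day 50 and low at day 300 beside all of these groups. The mast cell list lost its call with quantile normalization and with lowess centring, at medians no nearer to 0 than -0.40, and the neutrophil list lost its call, at -0.36, with the higher floor.

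Both DKmix arrays lay at least 2-fold apart from both day 3 arrays for 835 genes, 425 higher and 410 lower. The other ways of pairing the arrays gave 149 and 297 genes, the latter for the pairing that follows the control ratios. Against the eGFP array, which was not the reference of the earlier DKmix list medians, the mast cell list had medians of 3.42 at day 50 and 2.25 at day 300. The neutrophil list had -4.79 and -5.54, and the monocyte and dendritic cell list -1.50 and -2.13. The megakaryocyte list, at 1.14 over β-catenin day 3, had a median of -0.012 at day 50 over eGFP. Ribosome biogenesis genes had -0.83 at day 50 and -0.67 at day 300 over eGFP, against -1.68 and -1.49 over β-catenin day 3, and interferon-stimulated genes -1.20 and -0.69, against -1.67 and -1.09. Medians over eGFP were also nearer to 0 for the myeloid factors at day 50 (-0.18). At day 300 this held for the cyclin and p53-axis list (0.61) and the apoptosis regulators (0.30). The sign depended on the reference at day 300 for surface markers, at 0.52 over eGFP and -0.32 over β-catenin day 3. Erythroid genes had -0.35 over eGFP and 0.36 over β-catenin day 3. Cell cycle genes had -1.40 at day 50 and -0.42 at day 300 over eGFP. Across 7575 genes, which are not independent replicates, the ratio of DKmix day 300 to β-catenin day 3 correlated with that of DKmix day 50 to eGFP day 3, which shares no array with it (r = 0.38, Spearman's rho = 0.31). The same contrast with the arrays crossed, DKmix day 50 over β-catenin day 3 with DKmix day 300 over eGFP day 3, gave r = 0.23. The pairing of β-catenin over eGFP with DKmix day 300 over day 50, which follows the control ratios, gave r = 0.17. Differences between probe sets of the same gene (2769 genes) gave r = -0.036, -0.35 and 0.34 for these pairings, in the same order. The gene correlations are therefore not like measures.

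Identity checks on the sex-linked genes showed Eif2s3y above the floor on all 4 arrays, between 221.0 and 341.5, and Xist at 70.0 or less on each. Xist was above the floor on β-catenin day 3 and not above it on either DKmix array. Uty was at the floor on DKmix day 300 and between 87.4 and 139.5 on the others, and Kdm5d was at 30.0, below the floor, on β-catenin day 3 and between 61.1 and 99.2 on the others. Among the housekeeping genes, Actb had log2 ratios of -0.35, 0.39, -0.57 and -0.96 in the 4 comparisons in the order given here. Hprt had -1.20, 0.47, 0.59 and 0.11. Of the 14 housekeeping genes, 1 was past 2-fold for β-catenin over eGFP and 0 for DKmix day 300 over β-catenin day 3. For DKmix day 50 over β-catenin day 3, 5 were lower and 1 higher (median -0.37), with Tfrc at -2.33, Gusb at -1.91, Pgk1 at -1.51 and Ywhaz at 1.37. For day 300 over day 50, 4 were higher and 2 lower, with Gusb at 2.21.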

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

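The tests weighed in this part were chosen after the results were seen, except quantile and lowess scaling and the correlation of probe set differences, which were set before their values were known.

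For a set of named genes the 2 DKmix arrays lay on opposite sides of β-catenin day 3, each at least 2-fold away from it. The difference between the times was not tested, since each is 1 array. Higher at day 50 and lower at day 300 were Pdzk1ip1 (log2 ratio of day 300 over day 50, -5.75), Fos (-5.57), Selenop (-5.35), Cx3cr1 (-4.77), Cd244a (-4.72), Scin (-4.55) and Lyl1 (-2.19). Lower at day 50 and higher at day 300 were Plod2 (5.13), Hdc (4.97), Ramp3 (4.87), Cd68 (4.82), Anxa6 (3.28), Gfi1b (2.82), Nfil3 (2.74) and Tpx2 (2.35). For Tpx2, a spindle assembly factor, 1 of 4 probe sets had the opposite sign, at a log2 ratio of -0.93. Over all genes, 53 were higher at day 50 and lower at day 300, and 77 the reverse. The 3′ to 5′ control ratios also differed between these 2 arrays.

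Mast cell genes were high on both DKmix arrays. A 3′ signal bias is argued against for day 300, because the list median over β-catenin day 3, an array with like control ratios, was 2.18. Scaling that varies with intensity is argued against, since the lower of the quantile and lowess medians was 2.22. One scaling factor for an array stays open for the size of the difference, since scales set on single hybridisation controls gave medians from 0.613 to 1.89 at day 300. The list stayed at percentile 100 on the scale of all 9, but a single factor shifts the random lists alike, so that percentile tests nothing here. Whether the cytokine culture without the transgene could give the same genes stays open, with 0 eGFP arrays later than day 3, so the β-catenin transgene stays an untested explanation that cannot be told apart from time in culture.

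Neutrophil genes were low on the β-catenin day 3 array relative to eGFP. A lower share of progenitors in the eGFP culture, raising all other cell types alike, is argued against because the highest of 5 other cell type medians was 0.583 against 1.83 for neutrophil genes, both as eGFP over β-catenin. This covers only that version, since a cell type absent from both cultures could not rise. A lower share of progenitors with mainly neutrophils in their place was not tested and stays open. A 3′ bias of the eGFP array stays open, because the list median of DKmix day 50, also with high ratios, over eGFP was -4.79, but that of DKmix day 300, with low ratios, was -5.54, so the DKmix cells had too few of these transcripts to decide. Variation between cultures without regard to the transgene cannot be told apart from its effect, with 0 arrays per group beyond the first, and an effect of β-catenin stays an untested explanation.

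The high Gapdh 3′ to 5′ ratios of the eGFP day 3 and DKmix day 50 arrays may come from RNA breakdown in the cells or from labelling. For DKmix day 50, breakdown of the cells' RNA alone is argued against, since the thr, lys and trpn ratios of the bacterial controls were between 2.13 and 4.74 times the higher of β-catenin day 3 and DKmix day 300. For eGFP it stays open, as thr was 6.26 times but lys only 0.912 times that level. For a shared probe position effect on the gene ratios, differences between probe sets of the same gene across 2769 genes correlated between β-catenin over eGFP and DKmix day 300 over day 50, which share no array (r = 0.342, bootstrap SE 0.016). Part of the single-gene differences in the pairs that cross the 2 kinds of array is therefore likely to be technical, and no biological explanation was tested for the ratios.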

How the results depend on the processing

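Leaving out the eGFP day 3 and DKmix day 50 arrays and the scale set on the hybridisation controls were chosen after seeing the data. The other alternatives were planned. The deposited scale equals the scale used to within rounding, so it tests nothing.

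Counts of genes past 2-fold depended on the floor and on the probe set rule, while quantile normalization, lowess centring and leaving out cross-hybridising probe sets kept each within 1.5 times. For β-catenin over eGFP the 1365 higher and 1258 lower genes became 3529 and 3384 with the lower floor, 604 and 542 with the higher floor and 191 and 187 at 4-fold, and the lower count was 763 with the mean of all probe sets. For DKmix day 50 over β-catenin day 3 (2203 and 2162) they became 4462 and 4193, 1128 and 1271, and 463 and 538, with 1366 higher with the mean of all probe sets. For DKmix day 300 over β-catenin day 3 (1773 and 1828) they were 3523 and 4165, 1157 and 1009, and 478 and 361. For DKmix day 300 over day 50 (1972 and 2075) they were 3601 and 4565, 1263 and 1009, and 471 and 338, with 1127 lower with the mean of all probe sets. The 835 genes apart between DKmix and day 3 (425 higher, 410 lower) became 1808 (860, 948) with the lower floor, 538 (287, 251) with the higher floor and 209 (109, 100) at 4-fold. Without the 2 arrays named above only DKmix day 300 over β-catenin day 3 is left, whose 3601 genes past 2-fold meet a weaker criterion, so this count is higher by construction and tests nothing. A lower floor or threshold admits more genes and a higher one fewer by construction, and for the other changes the cause was not tested.

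A scale set on the mean of the 9 hybridisation control probe sets was run on the counts and list medians. It gave 3124 higher genes for β-catenin over eGFP, 700 higher and 5593 lower for DKmix day 50 over β-catenin day 3, 559 and 6049 for DKmix day 300 over β-catenin day 3, and 1663 (139, 1524) apart between DKmix and day 3. Of the 30 list calls, 23 were kept and 4 lost. The other 3 reversed in sign while still apart from random lists, namely the stem factors at day 50 (-0.27) and day 300 (-0.53) and the apoptosis regulators at day 300 (-0.47), all over β-catenin day 3. A single factor per array shifts the random lists alike, so calls could change only through the floor. Kept calls therefore test nothing about this scale. The mast cell list for β-catenin over eGFP came to stand apart (median -0.027, percentile 2.2). Over β-catenin day 3, the mast cell medians became 1.92 and 1.14, the megakaryocyte median at day 50 0.076 and the cyclin and p53-axis median at day 300 0.14.

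Of 30 list calls, 17 were kept under each of the other alternatives run on the lists. They included the mast cell, neutrophil, monocyte, interferon and ribosome biogenesis calls of both DKmix comparisons with β-catenin day 3, and the neutrophil and ribosome biogenesis calls at day 3. The mast cell median of day 300 over β-catenin day 3 ranged from 2.04 to 2.24. For β-catenin over eGFP, the interferon call was also lost with lowess centring, at 0.37, and the erythroid call with the lower floor, at -0.58, and without cross-hybridising probe sets, at -0.47. With the higher floor the interferon calls of DKmix day 50 and day 300 over β-catenin day 3 were kept at -0.81 and -0.64. The stem factor median of day 300 over β-catenin day 3 reversed to -0.0046 with the mean of all probe sets. Of 410 named gene values past 2-fold, 8 reversed under some alternative. With the mean of all probe sets, Rpl13a (0.0066), Sparc (1.80) and Tubb5 (-0.24) reversed for day 300 over day 50 and Tet2 (0.017) for β-catenin over eGFP. Rpl13a also reversed with quantile normalization (0.053). Without cross-hybridising probe sets, Dtx2 (0.51) reversed for day 300 over day 50, Fech (-0.67) for day 50 over β-catenin day 3, and Grasp (-0.56) and Maml1 (0.70) for β-catenin over eGFP. Their causes were not tested. Signal over background limits the neutrophil list, of which only 10 members were above the floor on either DKmix array.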

Other observations

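The hypoxia test in this part was chosen after the genes that prompted it were seen, and its threshold was set before the values of its list were known.

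Genes of a further kind stood out at day 300. Car9, a carbonic anhydrase, and Egln3, an oxygen-sensing prolyl hydroxylase, were named after their values were seen. Car9 was at 6552 on the DKmix day 300 array and 281.6 at day 50, and Egln3 at 1526 and 54.7. Eno3 and Plod2, which belong to the named genes, had log2 ratios of 4.84 and 5.13 for day 300 over day 50. Car9, Egln3 and Plod2 are known to respond to low oxygen in other cells.

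A hypothesis from these genes was that a hypoxia-type programme may be active on the DKmix day 300 array. It was tested on 46 other hypoxia-inducible genes, of which 41 were measured against β-catenin day 3, the array with like control ratios. Their median log2 ratio was 0.38 (14 at least 2-fold higher, 2 lower, percentile 99.5). This lies between the bound of 0.5 set for the hypothesis and the 0.25 set against it, so the test did not decide. Both bounds rest on equal overall intensity. A scale set on the hybridisation controls, brighter at day 300 by a mean log2 of 1.04, would lower this median and was not run on this list. Against DKmix day 50 the median was 1.06 (percentile 100), a comparison in which the control ratios also differed, and day 50 over β-catenin day 3 gave -0.40 (percentile 1.2). Culture density and oxygen were not recorded in the labels used here.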
